A study of Mus musculus with 10 samples.

How the data were processed

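ATAC-seq libraries were made from muscle stem cells of C57BL/6 mice, sorted by flow cytometry as α7-integrin and CD34 positive and held for 2 h with PGE2 or with vehicle, per the labels' protocols. Nuclei were treated with transposase and the fragments amplified by PCR, per the same protocols. PCR without molecular identifiers means that intervals cover counting error only. The 10 samples fall into 4 groups by age and treatment, as their titles give them.

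The reads were aligned with Bowtie2 to mm10 (GRCm38), per the submitters' processing notes. The deposited values are 2 peak lists in the narrowPeak layout of MACS, one for young and one for aged cells after PGE2. The version and options of the caller, the filtering of duplicate and mitochondrial reads, any shift of read ends to the cut site, and which libraries were pooled for each list are not given in the sources used here. The fold ratio of each summit is the deposited enrichment over background as the authors' caller gave it. The deposited −log10 p-value and −log10 q-value of each summit are the authors' too and belong to the peak, not to a comparison of ages. The smallest deposited −log10 q-value was 2.08 in the young list and 2.16 in the aged list. A fold is compared with other folds of its own list alone.

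The values showed how the caller worked. In both lists 100% of folds were whole multiples of a single step within a tolerance of 0.01, as (pileup + 1)/(background + 1) gives with 1 uniform background. The background came to 21.7 fragments in the young list and 19.8 in the aged list, and the smallest summit pileup to 39 and 37. The deposited −log10 p-value was equal to the Poisson tail of that pileup, checked below a −log10 p of 200. A uniform background takes no account of local copy number or mappability, so a stretch with more copies than the reference can pass the threshold. A list called from more fragments, or with a larger share of fragments in open chromatin, is longer at the same threshold, and the depth of each library is unknown.

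Rows that touch or overlap were merged into regions, with the strongest summit kept, which turned 265507 young rows into 131656 regions and 215838 aged rows into 117284. A region was shared if at least 1 bp was overlapped by the other list. Chance overlap was measured by shifting regions along their chromosomes 20 times. Strong regions were the top 10% by the caller's significance. Exact Clopper-Pearson intervals at 95% were computed over regions, and the floor of a count of 0 was taken as 3 counts. The SD over 19 autosomes describes unevenness along the genome and is not replicate error.

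Gene positions came from a RefSeq gene table of GRCm38.p6, which is the build of the lists, with 21887 protein-coding genes. The table gives the span of each gene, with no strand, exon or transcript start. Start sites as planned were therefore replaced by both ends of the span, exons and introns by the inside of a span, and the nearest start site by the nearest gene end within 100 kb of the summit. Some spans include predicted transcripts, so a promoter in use can lie inside the span and be missed. Vapa had no gene-end region with windows of 1 kb and one in both lists with windows of 2.5 kb. A search for sequence motifs was planned and not run, because no genome sequence was used here.

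The 21 gene lists were fixed before the data were examined and cover quiescence, myogenic differentiation, mature fibre, immediate early genes, PGE2 and cAMP signalling, cell cycle, senescence and p53, apoptosis, NF-κB, JAK-STAT, Notch, Wnt and TGF-β, Hox genes and chromatin regulators. They also cover fibroblast, endothelial, smooth muscle, immune and glial markers, genes of other organs and ubiquitous genes. All members were found by symbol. For each list the share of assigned regions found at one age was set against 10000 random gene lists of the same size, matched in 10 classes of the number of assigned regions. The percentile describes these 2 lists and is not a p-value for age. In a test on simulated data over 21887 genes, with 200 lists of 22 genes and a base share of 28%, 7% of unchanged lists fell outside the central 95%, and 88% of lists raised to 40% lay above it.

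Named genes and regions followed a rule fixed at the same time. It took for each age the 10 strongest autosomal regions of the top 10% without a counterpart, up to 4 members of each gene list (first those with a gene end open at one age, then the strongest open at both), 10 fixed genes (Pax7, Myf5, Myod1, Myog, Ptger2, Ptger4, Hpgd, Fos, Jun and Cdkn2a), and the 5 genes per age with the largest excess of one-age regions over the number expected from the overall split. The first part named no region.

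Settings fixed before the data were examined were a −log10 q of at least 5, the strongest 58642 regions of each list, a reciprocal overlap of 50%, summits within 100 bp, gene-end windows of 500 bp and 2.5 kb, other gaps and parts for strong regions, other merging of rows, and assignment within 50 kb, by gene body with 10 kb, or without gene-end regions. Added after the data were seen were a fold of at least 3, the top 50% of each list, the count expected from 20 classes of strength, 4 of width and the position of a region, and the removal of 100 kb stretches with 8 or more one-age regions. No library could be left out, since the values are pooled. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.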

Results

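Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in muscle stem cells sorted as α7-integrin and CD34 positive from young and aged C57BL/6 mice. These cells lie dormant beside the muscle fibre and rebuild it after injury. The cells were held for 2 h in culture medium with prostaglandin E2 (PGE2), a lipid signal of injured tissue that raises cAMP through some of its receptors, or with the vehicle, 0.1% DMSO. The labels describe 10 libraries, namely 2 young vehicle, 2 young PGE2, 3 aged vehicle and 3 aged PGE2. Young mice were 8 to 20 weeks old and aged mice 20 to 25 months. The values used here were 2 lists of accessible regions, one for young and one for aged cells, both after PGE2. The response to PGE2 against vehicle was not analysed here. The comparison was therefore between ages after the same treatment, and it addressed how chromatin accessibility of these cells differs between ages after PGE2. An age difference present without PGE2 cannot be told apart here from one in the response to PGE2. Each age had a single list with no value per library, so no difference between the ages carries a replicate error or a p-value. Binomial intervals below cover counting error over regions and do not stand for mice.

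After PGE2 most gene ends with a region had one at both ages, and the young list held more regions. Presence in both lists does not compare how open a site was. The young list held 131656 regions with a median width of 435 bp, covering 92.2 Mb of the GRCm38 genome. The aged list held 117284 regions with a median width of 380 bp, covering 71.6 Mb. The ratio of young to aged was 1.12 for the number of regions and 1.29 for the length covered. At 10-fold or more over background, as the authors' peak caller gave it, the young list had 38189 regions and the aged list 29766. The number of libraries behind each list and the number of reads in each library are unknown. The uniform background that the caller used could be recovered from the values and was 21.7 fragments in the young list and 19.8 in the aged list, a ratio of 1.10. Heights were not compared between the lists, and a rank in lists of different length shows no change by itself. Folds of both lists printed for a gene below are therefore no measure of change. The ubiquitous genes Eef1a1, Pgk1 and Rpl13a also had higher gene-end folds in the young list (146, 98.1 and 84.3) than in the aged list (113, 65.8 and 57.8).

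Of the young regions, 94504 (71.8%, 95% exact binomial interval 71.5 to 72.0) were overlapped by an aged region by at least 1 bp. Of the aged regions, 104682 (89.3%, 89.1 to 89.4) were overlapped by a young region. These shares varied little along the genome, with an SD over the 19 autosomes of 1.25 and 1.75 percentage points. Regions shifted along their chromosomes were overlapped in 5.45% ± 0.11 (SD, 20 shifts) of young and 6.37% ± 0.14 of aged cases. The regions without an overlap numbered 37152 in the young list, called young-only here, and 12602 in the aged list, called aged-only. They were narrow and weak. Young-only regions had a median width of 220 bp and a median fold of 2.73 over background, against 629 bp and 7.57 for young regions with an overlap. Aged-only regions had a median width of 193 bp and a median fold of 2.40, against 430 bp and 5.0. Young-only regions made up 10.7% of the length covered by the young list, and aged-only regions 3.90% of that covered by the aged list. When the 58642 strongest regions of each list were compared, 84.6% of young regions and 88.9% of aged regions were overlapped. That setting both equalises the number of regions and drops the weak ones. A region counted there as one-age can overlap a region of the other list that was cut.

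**Figure D1:**
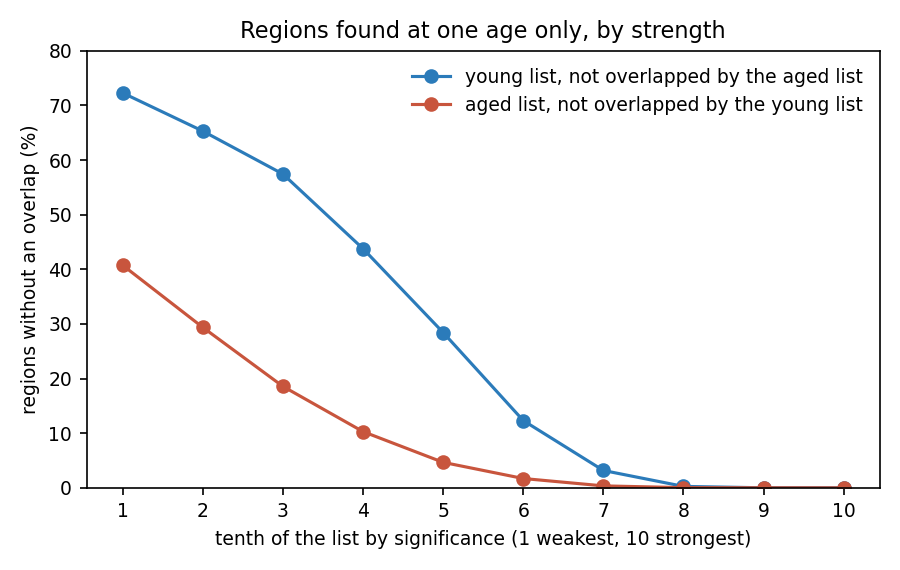
Percent of regions without an overlap in the other list (vertical axis) in each of 10 classes of a list by the caller's significance (horizontal axis, 1 weakest to 10 strongest), for the young list (blue) and the aged list (red). The share fell from 72.3% in the weakest class to 0 in the strongest class of the young list, and from 40.7% to 0 in the aged list.

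None of the strongest open sites was found at one age alone. In the strongest 10% of each list, 0 of 13161 young regions and 0 of 11722 aged regions lacked a region of the other age within 1 kb, which allows shares of up to 0.0228% and 0.0256%. Among regions of at least 10-fold, 25 young and 2 aged regions had no counterpart within 1 kb. The rule fixed for naming strong one-age regions therefore named none. The regions that follow were picked after their values were seen, from the 10 strongest of each list on autosomes without a counterpart within 1 kb. In the young list the strongest lay on chromosome 1 at 128856646 to 128857625, 14.0-fold over background and more than 100 kb from any protein-coding gene end. Others lay 81728 bp from Klhl25 on chromosome 7 (75955415 to 75956227, 13.9-fold) and inside a gene span near Brip1, which encodes a DNA repair helicase, on chromosome 11 (86106623 to 86107257, 12.1-fold). Another lay inside a gene span, 1148 bp from an end of Hsph1, a heat shock chaperone gene, on chromosome 5 (149617705 to 149619481, 11.9-fold). Young regions stronger than those near Brip1 and Hsph1 were passed over, among them those nearest Hydin (12.8-fold), Zfp329 and Ppp4r1 (12.7-fold each). In the aged list the strongest lay on chromosome 16 at 98107441 to 98107619, between genes, with a fold of 15.3. It was followed by a region inside a gene span near Anks1b on chromosome 10 (89877078 to 89877376, 12.1-fold). The next lay inside a gene span near Ostn, which encodes the muscle and bone peptide osteocrin, on chromosome 16 (27349147 to 27349631, 8.89-fold).

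Gene ends, at either the start or the finish of a gene since strand was not used, were open at both ages for most genes that had any region there. Of 21887 protein-coding genes, 13855 (63.3%) had a region within 1 kb of an end of the gene span in both lists, 700 (3.20%) in the young list only, 105 (0.480%) in the aged list only, and 7227 (33.0%) in neither. Gene ends open at one age mostly had weak regions. The median percentile of such a region within its own list was 31.8 for young-only and 14.2 for aged-only gene ends, and 126 of the 700 young-only regions lay above the median of their list. For 87 of the 700 young-only and 15 of the 105 aged-only gene ends the region was itself overlapped in the other list, outside the 1 kb window. Which genes fell in these classes depended on the setting. Of the 700 young-only genes, 485 kept their class with windows of 500 bp, 472 with 2.5 kb and 643 at the stricter threshold. For the 105 aged-only genes these numbers were 64, 57 and 67. When the strongest regions of each list, equal in number, were compared, 98 young-only and 11 aged-only genes kept their class. That cut removes most of these weak regions themselves, so few genes could keep it.

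Genes of stem cell identity and dormancy were open at both ages without exception among those listed. All 28 genes of the quiescence list had a gene-end region in both lists. Pax7, the transcription factor that marks muscle stem cells, lies on chromosome 4 (139737059 to 139833530) and had gene-end regions of 26.7-fold in the young list and 16.6-fold in the aged list. It had 73 regions assigned in the young list and 60 in the aged list, of which 24 were young-only and 4 aged-only. Among the strongest regions in equal number the counts were 3 and 3, and with reciprocal overlap 39 and 26. Myf5, an early myogenic regulator on chromosome 10 (107482908 to 107486927), had 7 and 6 assigned regions, 2 of them young-only and 1 aged-only. Foxo3, Itgb1, Cdkn1b and Gas1 had gene-end regions above the 98th percentile of both lists. Young-only regions made up 178 of 718 assigned regions (24.8%, 95% interval 21.7 to 28.1) of this group, at the 13.3th percentile of 10000 random gene lists matched on the number of assigned regions. Aged-only regions made up 7.12% of its aged regions, at the 3.18th percentile, and below the range in 1 of 10 settings.

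The genes that take a stem cell into muscle differentiation had the highest young-only share relative to random lists. Of 172 young regions assigned to this group, 69 (40.1%, 32.7 to 47.9) were young-only, where the central 95% of random lists ran from 20.8% to 37.7%, a percentile of 99.3. At gene ends, 14 of its 22 genes had a region at both ages, 6 in the young list only and 0 in the aged list only. The genes named by the fixed rule were Mymx, Mymk, Ttn and Actc1. Mymx and Mymk encode the proteins that fuse myoblasts, Ttn encodes the giant sarcomere protein titin, and Actc1 an actin of developing muscle. Their young gene-end regions had folds of 14.0 for Mymx (chromosome 17, 45597800 to 45600205), 6.03 for Ttn, 3.92 for Mymk and 3.83 for Actc1. With windows of 2.5 kb, Mymx and Ttn had a gene-end region in both lists, while Mymk and Actc1 stayed young-only. With windows of 500 bp, Mymx, Mymk and Ttn had one in neither list, and Actc1 stayed young-only. Among the strongest regions in equal number, Mymk and Actc1 had one in neither list, while Mymx and Ttn stayed young-only. Mymx had 0 young-only and 1 aged-only region among its 2 young and 3 aged assigned regions. A gene-end region can be assigned to another gene, so these counts do not show whether that of Mymx was overlapped in the aged list. Myod1, the commitment factor on chromosome 7 (46376474 to 46379092), was open at both ages, at 83.3-fold in the young list and 39.7-fold in the aged list. Of its 9 young assigned regions 6 were young-only, and 0 of its 8 aged regions were aged-only. The counts were 0 and 0 among the strongest regions in equal number, and 7 and 6 with reciprocal overlap. Myog, the differentiation factor on chromosome 1 (134290004 to 134292548), had weak gene-end regions at both ages, 3.57-fold and 3.65-fold. Of its 8 young assigned regions 4 were young-only, and 0 of its 4 aged regions were aged-only. In equal number Myog had neither a gene-end region nor a one-age region. The share of this group lay inside the central range when regions were assigned within 50 kb (percentile 94.4), by gene body (74.9), with gene-end regions left out (96.1) or at 3-fold and above (96.8). With 42 shares examined, 2.1 would fall outside the central 95% by chance at the nominal rate, and 2 did.

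**Figure D2:**
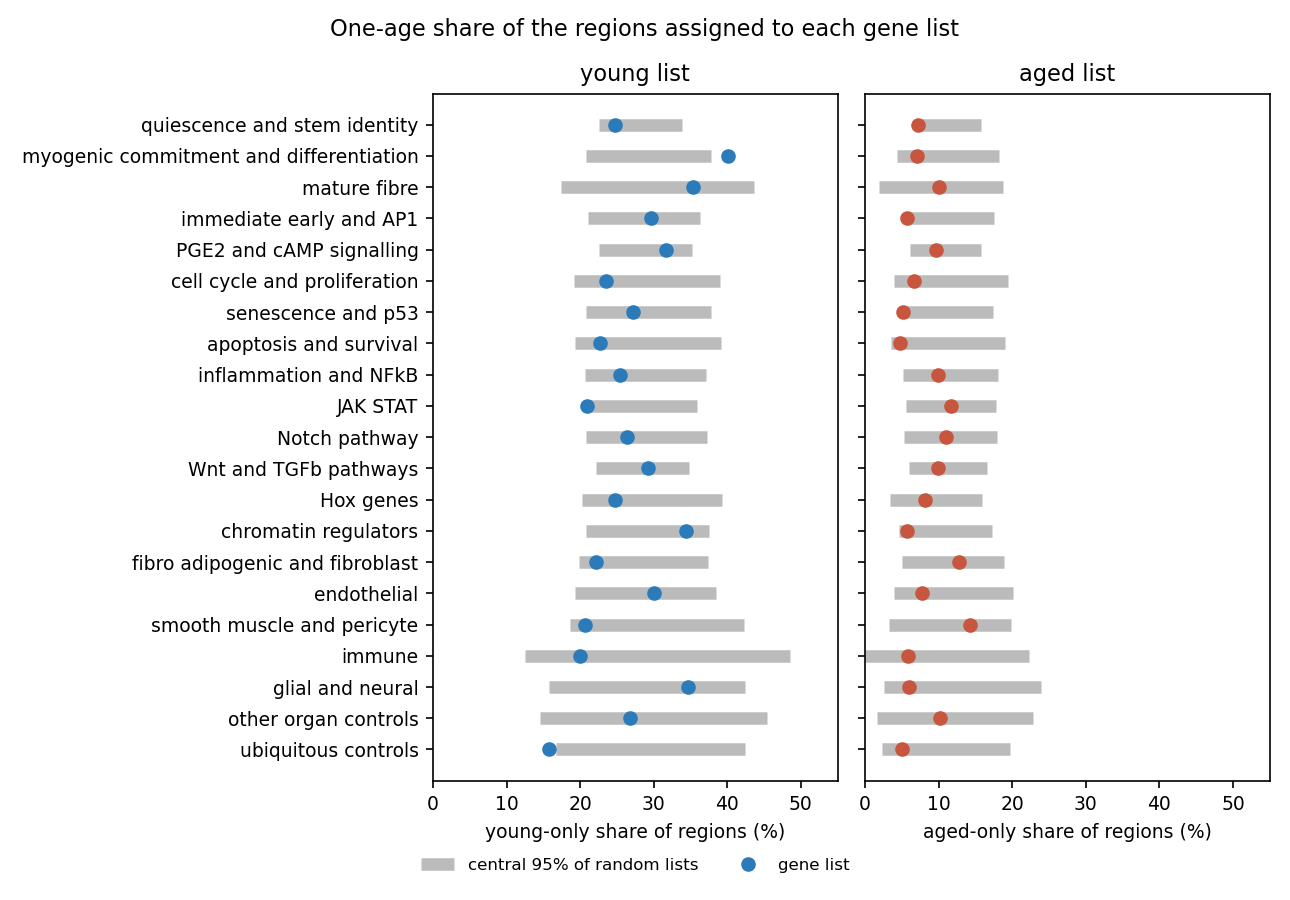
One-age share of assigned regions in percent (horizontal axis) for each of the 21 gene lists (rows), with young-only shares on the left and aged-only shares on the right; points are the lists and grey bars the central 95% of 10000 matched random lists. Myogenic commitment and differentiation lay above the bar at 40.1% and ubiquitous controls below it at 15.8%, both in the young list.

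Mature fibre genes gave a young-only share of 35.4% (percentile 80.1) and an aged-only share of 10% (67.0), with the young-only share above the range at equal length (99.6). Myh4, a fast myosin heavy chain gene, had a gene-end region in the young list only (4.27-fold), while Mylpf, Actn3 and Casq1 were open at both ages. The second share outside the random range belonged to ubiquitous genes such as Eef1a1 and Pgk1. In that group 15 of 95 young regions (15.8%, 9.12 to 24.7) were young-only, below the range of 16.7% to 42.5% at a percentile of 1.67, and this held in 5 of 10 settings. Its aged-only share was 5.05% (17.0). One of its genes, Ywhaz, had a young-only gene-end region, at 2.47-fold.

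Most genes of the PGE2 pathway had a gene-end region at both ages. Of 35 genes for PGE2 synthesis, receptors and cAMP signalling, 30 had a gene-end region in both lists, 1 in the young list only and 4 in neither. Ptger4, which encodes the EP4 receptor, lies on chromosome 15 (5233399 to 5244187) and had gene-end regions of 184-fold in the young list and 125-fold in the aged list. Ptger2, which encodes EP2, had a gene-end region of 4.97-fold in the young list and 2.11-fold in the aged list, the latter near the caller's floor and lost at a stricter threshold. Ptger3, which encodes EP3, had a gene-end region in the young list only, at 2.91-fold. The kinase gene Prkaca and its target factor gene Creb1 were open at both ages, above 99-fold in each list. The young-only share of this group was 31.7% (percentile 83.7) and the aged-only share 9.57% (44.3). Among the strongest regions in equal number its young-only share was 8.25%, below the range at a percentile of 1.15.

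Hpgd, which encodes the enzyme that breaks down PGE2, went against the overall split of one-age regions. It lies on chromosome 8 (56294552 to 56321046) and had 10 assigned regions in the young list and 17 in the aged list. Of these, 1 was young-only and 9 were aged-only, although 77.3% of all one-age regions assigned to genes were young-only. Its gene end was open at both ages, at 8.80-fold in the young list and 13.8-fold in the aged list. The count was 0 young-only against 5 aged-only among the strongest regions in equal number, and 1 against 6 at the stricter threshold. Both settings cut weak regions, so an aged-only region there can overlap a young region that was cut. These counts are therefore no separate support. Hpgd was named before the data were examined, as 1 of 10 genes, and its regions lie side by side and are not independent.

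Immediate early genes mostly had regions at both ages. Of 22 immediate early and AP-1 genes, 21 had gene-end regions in both lists and 1 in neither. Fos had 26 young and 24 aged assigned regions, with 6 young-only and 1 aged-only. Jun had 15 and 18, with 3 young-only and 3 aged-only. Klf6, Fosl2 and Egr1 were above the 99th percentile at the gene end in both lists. The young-only share of the group was 29.6% (percentile 63.5) and the aged-only share 5.70% (2.88), the latter below the range in 2 of 10 settings. Inflammation and NF-κB genes, with Cebpd, Nfkbia, Cxcl1 and Tnfaip3 open at both ages, gave 25.4% (24.7) and 9.96% (52.7). Of those 21 genes, 17 had gene-end regions in both lists and 4 in neither. In the JAK-STAT group the young-only share was 20.9% (2.73) and the aged-only share 11.7% (70.0), with the young-only share below the range in 4 of 10 settings. Socs3, Cish and Il6st of this group were open at both ages, while a gene end of Lifr, a cytokine receptor gene, had a weak aged-only region (1.92-fold).

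Genes of senescence and p53 had an aged-only share of 5.08% (percentile 2.54), at the lower edge of the random range, and a young-only share of 27.1% (34.7). The aged-only share lay below the range in 4 of 10 settings and above it in 1, with reciprocal overlap (percentile 99.6). Cdkn2a, which encodes the senescence protein p16, lies on chromosome 4 (89274473 to 89294619). It had a gene-end region in both lists, at 47.5-fold in the young list and 25.3-fold in the aged list. These regions lay at the higher-numbered end of the span (89294143 to 89295902 in the young list). Transcript starts were not used, so they are not tied to the start of the p16 transcript. Cdkn2a had 3 young-only and 0 aged-only regions, 3 and 1 at the stricter threshold, and 0 and 0 among the strongest regions in equal number. Cdkn1a, which encodes p21, had an aged-only gene-end region that was weak, at 2.07-fold. With windows of 2.5 kb it was open at both ages, as were Lifr, Ly6a, Axin2, Cdh5, Myh4 and Ywhaz, which are named here for a gene end open at one age. Gadd45a, Gadd45b and Trp53inp1 were open at both ages. Cell cycle genes gave 23.5% young-only (16.7) and 6.67% aged-only (19.4), the latter below the range in 3 of 10 settings, with all 22 open at the gene end in both lists, Ccna2, Mcm3, Cdk2 and Pcna among them. Apoptosis and survival genes such as Apaf1, Bax and Bcl2l11 gave 22.8% (11.5) and 4.70% (6.42).

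Signalling, patterning and chromatin groups lay inside the random range in both lists in the setting reported. Notch pathway genes gave 26.3% young-only (percentile 31.1) and 10.99% aged-only (63.7), with Hey2, Numb and Maml2 open at both ages and Rbpj, the nuclear partner of Notch, with a young-only gene-end region (2.69-fold). Wnt and TGF-β genes gave 29.2% (63.8) and 9.90% (48.0), with Fzd4, Fzd7 and Id2 open at both ages and Axin2 with a young-only gene-end region (3.08-fold). Hox genes, including Hoxa3, Hoxa9, Hoxc6 and Hoxc10, gave 24.8% (16.2) and 8.13% (44.6). Their young-only share lay below the range at 3-fold and above (percentile 0.235) and at equal length (0.740), and their aged-only share above it with reciprocal overlap (98.7). Chromatin regulators, including Kdm6a, Tet2, Ezh2 and Hdac2, gave 34.4% (90.6) and 5.75% (7.47).

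Markers of other cell types that the sort could have let through lay inside the random range in both lists, with exceptions in other settings given with each group. Fibro-adipogenic and fibroblast genes, among them Dpt, Fbn1 and Gsn, gave 22.1% young-only (percentile 8.15) and 12.7% aged-only (79.0), and at 3-fold and above the aged-only share was 14.3% (98.0), above the range. A gene end of Ly6a, which encodes the Sca-1 antigen, had an aged-only region at 2.499-fold. Endothelial genes gave 30.1% (65.9) and 7.69% (29), with Tek, Erg and Cldn5 open at both ages and Cdh5 with a young-only region at 1.98-fold. Smooth muscle and pericyte genes such as Acta2, Pdgfrb and Kcnj8 gave 20.6% (5.89) and 14.3% (86.4). At 3-fold and above these shares were 10.3%, below the range (0.165), and 15.6%, above it (98.4). The young-only share was also below the range with reciprocal overlap (1.85), and the aged-only share above it against the share expected from strength (97.53). Without dense stretches the aged-only share was 8.86% (42.3). Immune genes gave 20.0% (16.6) and 5.88% (40.5). Of 15 immune genes, 5 had gene-end regions in both lists, among them Spi1, Cd68, Cd79a and Coro1a, and 10 in neither. All 11 smooth muscle and pericyte genes and 13 of 15 fibro-adipogenic and fibroblast genes had gene-end regions in both lists. So did 8 of 14 endothelial and 6 of 8 glial and neural genes. An open gene end by itself therefore does not set stem cells apart. Glial and neural genes gave 34.6% (85.0) and 6.00% (20.0), with Ncam1 and Cadm2 open at both ages and Sox10 with a young-only region at 2.95-fold. Genes specific to other organs gave 26.8% (43.9) and 10.2% (64.2). Of those 20 genes 17 had no gene-end region in either list, and Sftpc, Apob and Apoa1 had one in both. A gene-end region can belong to a neighbouring gene. Sftpc had 0 assigned regions in both lists, because the summit of its gene-end region lay nearer to an end of another gene. The same held for Pcna in both lists and for Cd68 in the young list.

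Some neighbourhoods held many one-age regions. For the young list, the number of 100 kb stretches with 8 or more young-only regions, 622, was within what shuffling among regions of like strength gave (median 609.5, highest 659 of 100 shuffles). Atp2b1, which encodes a plasma membrane calcium pump, lies on chromosome 10 (98914630 to 99026143) and had 31 young-only and 0 aged-only regions. Ddr2, a collagen receptor gene on chromosome 1 (169972307 to 170110836), had 34 and 1, and Col4a2, a basement membrane collagen gene on chromosome 8 (11312805 to 11449287), had 28 and 0. Pakap on chromosome 4 had 34 and 2, and Vapa on chromosome 17 had 27 and 0. In the other direction, Hmcn2 on chromosome 2 (31314255 to 31460738), which encodes hemicentin 2, an extracellular matrix protein, had 13 young-only and 46 aged-only regions. Sulf1, which encodes an enzyme that edits heparan sulfate, lies on chromosome 1 (12692197 to 12861192) and had 2 and 34. Prl2c3 on chromosome 13 had 2 and 26, and the zinc finger genes Zfp982 and Zfp992 on chromosome 4 had 0 and 21 and 0 and 20. The last 3 genes lie beside close relatives, and their values are uncertain where reads are shared between copies. Among the strongest regions in equal number, most of these differences were small or gone. One-age regions are mostly weak, so that setting drops most of them whatever their cause. A count that remains can come from a counterpart that was cut. In that setting Atp2b1 had 2 young-only and 1 aged-only region, Ddr2 5 and 1, Col4a2 1 and 0, Vapa 1 and 0, and Pakap 1 and 3. In the other direction, Hmcn2 had 1 young-only and 3 aged-only regions, Prl2c3 0 and 0, Zfp992 0 and 3, Zfp982 0 and 8, and Sulf1 0 and 14.

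**Figure D3:**
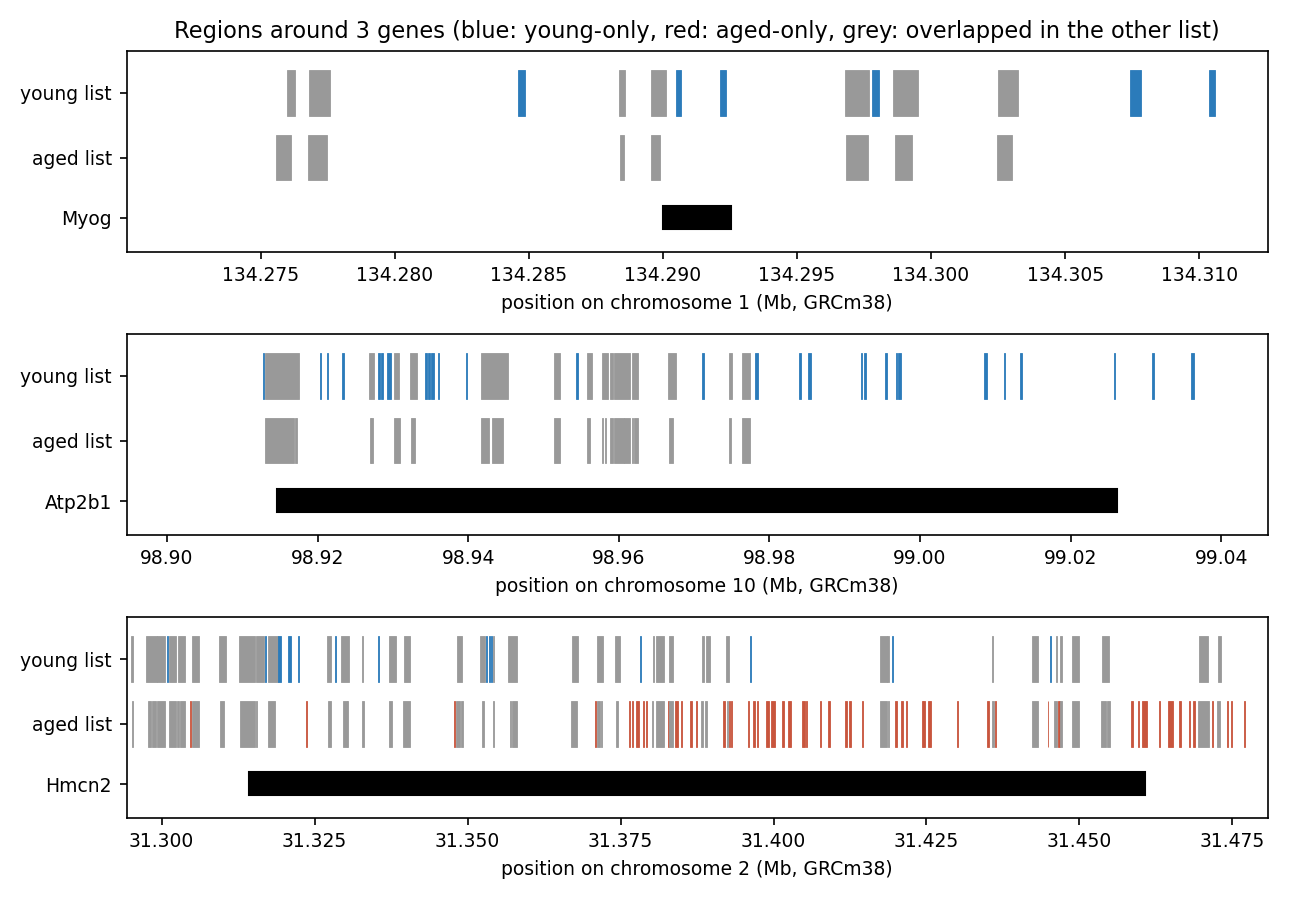
Maps of Myog, Atp2b1 and Hmcn2 with 20 kb on each side, with position in Mb on the horizontal axis, young and aged regions as boxes (blue young-only, red aged-only, grey overlapped in the other list) and the gene span in black. The window of Myog held 6 young-only and 0 aged-only regions, that of Atp2b1 28 and 0, and that of Hmcn2 14 and 54.

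One-age regions lay away from gene ends more often than shared ones. The shares were not matched on strength or width, and one-age regions were weaker and narrower, so the contrast is not tied to age. Among young regions on placed chromosomes, 14.2% of those with an overlap (SD over 19 autosomes 2.71 percentage points) and 6.00% of young-only regions (SD 1.26) lay within 1 kb of a gene end. Young-only regions lay inside genes in 57.4% of cases, against 47.4% of young regions with an overlap. Aged-only regions lay at gene ends in 4.71% of cases (SD 1.44), inside genes in 49.5% and between genes in 45.8%. For aged regions with an overlap the same shares were 14.4%, 48.3% and 37.3%. With windows of 2.5 kb the shares at gene ends were 14.5% for young-only and 12.7% for aged-only regions. These cannot be set against the shares of regions with an overlap given above, which are for windows of 1 kb.

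The sex of the mice is not given in the labels used here. Chromosome X held 2743 regions (2.08%) of the young list and 2469 (2.11%) of the aged list. The Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y had gene-end regions in both lists. Chromosome Y held 27 young and 36 aged regions, and no region lay on mitochondrial DNA in either list.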

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

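The at-least-3-fold, top-50%, expected-from-strength and dense-stretch settings were chosen after seeing the data. No paired analysis was possible because the values are pooled per age with no value per library, and leaving out a replicate was not possible for the same reason. The planned motif shares and their alternatives were not run. Reciprocal overlap gave no value for strong regions and gene-end classes, which are defined by distance. The share of young regions overlapped by aged ones, 71.8%, became 84.6% at equal length, 58.8% with reciprocal overlap, 64.0% by summits and 74.4% at 3-fold. The share of aged regions overlapped by young ones, 89.3%, became 91.0% at the stricter threshold, 88.9% at equal length, 66.1% with reciprocal overlap, 71.8% by summits and 93.2% at 3-fold. It stayed above the young share in each of these settings. The gene-end share of young-only regions, 6.00%, became 7.89% at equal length, 6.91% with reciprocal overlap, 6.26% without dense stretches and 14.5% with windows of 2.5 kb. That of aged-only regions, 4.71%, became 4.12% at the stricter threshold, 3.11% at equal length, 9.57% with reciprocal overlap and 12.7% with windows of 2.5 kb, so the order of these shares turned with reciprocal overlap. Without merging, the lists had 265507 young and 215838 aged entries. Strong regions without a counterpart numbered 1834 young and 187 aged in the top 50%, and 1 aged in the top 20%. The number of gene lists with a young-only share outside the random range, 2 in the report, was 6 at equal length, 4 at 3-fold, 1 within 50 kb, 1 for distal regions, 1 against the share expected from strength and 0 by gene body. The number with an aged-only share outside, 0 in the report, was 1 at the stricter threshold, 2 at equal length, 2 with reciprocal overlap, 1 within 50 kb, 2 by gene body, 1 for distal regions, 3 against the share expected from strength, 2 at 3-fold and 1 without dense stretches. The young-only share of myogenic genes fell inside the range within 50 kb (94.4), by gene body (74.9), for distal regions (96.1) and at 3-fold (96.8), and it lay above the range in 6 of 10 settings. The ubiquitous genes lay below it in 5 of 10. The excess of young-only regions at Pakap turned to -1.49 at equal length. Most one-age regions are cut in that setting, and others can arise there from a counterpart that was cut. The causes of these shifts were not tested. Depth may limit weak regions most, which was not tested. The smallest pileup called was 39 fragments in the young list and 37 in the aged list.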

Other observations

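In this part, the tests of immediate early genes, of gene families, of copy number and of both explanations for list length were chosen only after the results were seen, and so were the chaperone and endoplasmic reticulum stress gene lists.

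Heat shock chaperone genes, which no list of the report covers, had gene ends open at both ages in all 36 cases examined. Young-only regions were plentiful around 6 of them noticed in the data, with 18 at Bag3, 15 at Hsph1, 14 at Hspa8, 10 at Hspa9, 6 at Hspd1 and 6 at Hspe1. At these 6 genes 69 of 93 young regions (74.2%) were young-only. Of 30 further chaperone genes, 23 had a young-only region, with 10 at Dnajb6, 9 at Cct8 and 5 at Hspa1b, while Fkbp5 and Hsf2 had 0 young-only against 4 and 5 aged-only. Of 24 genes of the endoplasmic reticulum stress response, 16 had a young-only region too, so such a region by itself does not set chaperone genes apart. Those 24 genes had 28 of 131 young regions (21.4%) young-only, at the 3.51th percentile of random lists.

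The first pattern weighed is that young-only regions are dense around heat shock chaperone genes. At the 30 chaperone genes not looked at beforehand the young-only share was 38.3% (95% interval 30.9 to 46.2), at the 97.05th percentile of matched random lists, just inside the central 95%, and a general excess of weak regions at region-rich genes stays open by that measure. Divided by the count expected from strength, width and position, it lay at the 89.07th percentile, so the strength of regions stays open as well. The share of the same 30 genes lay above the range by gene body (99.87) and for distal regions (98.99). It lay inside the range at 3-fold (30.3), at the stricter threshold (79.2) and without dense stretches (41.5). Among the strongest regions in equal number it lay below the range (1.29), so the pattern may rest on weak regions. A stress response to cell isolation that moves all early stress genes could not be told apart, since the upper bound for immediate early genes, 35.3%, lay above the chaperones' lower bound of 30.9%, and a biological difference with age was not tested. Taken alone, the immediate early share of 29.6% showed no excess over random lists (percentile 63.5). The bounds treat regions that lie side by side as independent, so their overlap does not settle the question.

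The second pattern is that some aged-only regions, 770 or 6.11% of them, are packed into 66 stretches of 100 kb with 8 or more each. Chance placement is argued against, since the highest number in 100 shuffles among regions of like strength was 27, whereas the 622 young stretches did not exceed their shuffles (highest 659). Reads shared between copies of a gene family may account for part, since 17 of 65 stretches on placed chromosomes had, within them or next to them, genes that share a symbol stem, at the 99.99th percentile of random stretches. The other 48, those of Sulf1 and Tshz2 among them, had no such genes, which does not exclude copies with unrelated symbols. Several of the stretches with such genes lie side by side, as on chromosome 4, whereas the random stretches were drawn singly. The percentile is therefore overstated. A gain in copy number in the aged mice, or a strain variant against the reference, could not be told apart: the median summit pileup of aged-only regions in these 48 stretches was 51, against 49 elsewhere, and the caller's floor of 37 lies so near the doubled background of 39.6 that the test could hardly fail.

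The third pattern is that the young list is longer than the aged list. The number of fragments behind each list is argued against as the whole cause by the plain counts at 3-fold alone, if the caller extended fragments alike in both. The young list held 95662 regions of 3-fold or more, against 81577 in the aged list. When the young pileups were thinned at random to the aged background, at least 95753 such regions were left in each of 100 draws. Thinning could hardly lower a count at a fixed fold, since pileup and background fall together. It therefore adds nothing to the plain counts. A lower share of fragments in open regions in the aged libraries could not be told apart from a biological loss of open sites with age, since 0 percent of the strongest 10% of the young list lacked an aged region within 1 kb, which any of these would leave, and neither was tested with values per library.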
